A study of Mus musculus with 16 samples.

How the data were processed

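Colon samples of 16 mice were used, 4 each of WT on water, WT on DSS, KO on water and KO on DSS, as the sample labels name them. Per the labels each sample is a separate mouse. The deposited data were 2 tables with the same counts, 1 of them with a taxonomic name for each of 1901 ASVs. The authors brought the deposited counts to 96469 in every library, and the table's title calls it even. Whole numbers remained, so the counts were probably subsampled, and the depth before that step is not given in the sources used here. The equal totals remove differences in depth between libraries but not the coupling of shares, in which a rise of one taxon lowers the share of the others. The amplicon region, the ASV caller and the taxonomy database are not given in the sources used here. Per the labels' protocols RNA was extracted and libraries were made as for RNA-seq, and the submitters' processing notes list the mouse builds GRCm38 and mm10. Neither applies to a table of 16S counts, and the series design names 16S sequencing, so the counts were taken as 16S counts, and whether the template was DNA or RNA is open. No mouse genome was used here.

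Counts were summed per genus. ASVs without a genus name were summed under their lowest named rank as "unclassified", which gave 146 groups, 114 of them named genera. Of the ASVs, 977 had a genus name and held 58.6% of counts, 51 had no kingdom (0.0284% of counts) and 0 were of chloroplasts or mitochondria. Groups were kept with at least 10 counts in all and counts in at least 3 libraries, which left 122 groups and 1056 ASVs. The main test was edgeR 4.0.16 (glmQLFit with robust=TRUE, glmQLFTest) in R 4.3.3 on the deposited counts, with the library total as the only scaling and all 16 libraries in 1 fit with a mean per group. P-values were adjusted by Benjamini-Hochberg and called at an FDR of 0.05. The interaction is the DSS effect in KO minus that in WT mice.

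The Shannon index (natural log), observed ASVs and shares of counts were compared by two-sided exact permutation tests over all 70 arrangements of 4 against 4 mice, whose smallest p is 0.0286. Interactions of these values used 4900 arrangements of genotype within treatment after removal of the additive genotype effect, an approximate test that called 7.5% of 200 simulations without an interaction. Bray-Curtis distances were tested over the 35 splits of 8 mice, and in a fit with both factors by adonis2 of vegan 2.7.1 with 10000 permutations. Shares were tested for 10 phyla, families with at least 1% in a group mean and 15 of 16 fixed lists, with Benjamini-Hochberg adjustment within level and comparison. For the log2 scale of shares, 0.01% was added to each share. The lists were the anaerobic Clostridia families, butyrate-producing genera, Enterobacterales, Gram-positive cocci, mucin-degrading genera, Muribaculaceae, lactobacilli and bifidobacteria, Erysipelotrichales, mucus-associated genera, sulfate reducers, Prevotellaceae, Rikenellaceae, Sutterellaceae, the coprostanoligenes group, reagent-associated genera and organelle sequences, the last with 0 ASVs. Permutations were run in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures drawn with matplotlib 3.10.9.

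Tests, lists and the rule for named taxa were fixed before the data were examined. The rule took, per pairwise comparison, up to 10 groups each with the highest and lowest log2 fold change among those past the threshold with at least 0.1% in either group mean. It also took the 5 lowest p-values of the interaction, list members with at least 0.5% in a group mean, the 10 most abundant groups and up to 3 ASVs per direction and comparison with the largest change. A few further names are marked in the text as chosen after their values were seen. In the interaction all 11 groups past the threshold are named, those beyond the 5 lowest p-values after they were seen. A fold is the ratio of mean shares. Where all libraries of a group were at 0 it is a lower bound against 3 counts per library, and none is given where a group mean was above 0 but under that floor.

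Alternatives were TMM scaling, median-ratio size factors on positive counts, DESeq2 1.42.0, limma 3.58.1 on centred log-ratios with pseudocounts of 0.5 and 1, no filter, a filter of 6 libraries, a replicate block, removal of 10 ASVs of reagent-associated genera, only the compared groups, other diversity indices and distances, and each mouse left out. Another was added after seeing the data. In each DSS group, ASVs whose group mean was under 5% of that in the other DSS group were set to 0, which took 86 ASVs and 1.21% of counts in WT and 84 ASVs and 1.89% in KO mice. It is called "traces set to 0" in the text. Interactions of genera with a group mean under 3 counts per library were also given with that mean set to 3 counts, again chosen after the values were seen, as was leaving out each mouse for named genera. Whether chance could give the interaction calls on centred log-ratios was tested with 100 splits of genotype within treatment after removal of the additive genotype effect.

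The tests were tested on simulated data before use, with counts of each taxon drawn independently from its mean over all 16 libraries and the fitted spread. The simulation held neither equal library totals, nor the real group differences, nor traces between groups. Its rates may not carry over to data with these. In 122 simulated genera, 10% to 26.2% of 4-fold, 60% to 73.8% of 16-fold and 83.8% to 93.8% of 256-fold changes were called over the 4 pairwise comparisons, and 2.84% to 5.16% of calls were of unchanged genera. In 1056 simulated ASVs, 0% to 1.49%, 13.4% to 15.7% and 45.5% to 54.5% were called. Small changes can therefore go uncalled. Libraries of a group differed far beyond sampling noise (chi-square per degree of freedom 50.8 to 167.4), so none was counted as a repeat of another.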

Results

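The bacteria of the colon were profiled by 16S rRNA gene sequencing in 16 mice, 4 in each of 4 groups. Wild-type (WT) mice and mice lacking Mertk (KO), both on the C57BL/6J background, drank plain water or 2.5% dextran sulfate sodium (DSS) for 7 days, and the colon was collected on day 8. Mertk is a receptor tyrosine kinase with which macrophages take up dying cells, and DSS is a sulfated polysaccharide that injures the colonic epithelium and causes colitis. The table held 1901 amplicon sequence variants (ASVs, distinct 16S sequences), and every library had the same total of 96469 counts. A count of 0 therefore allows a share of up to 0.00311%, counting error only. Counts of 16S sequences do not measure Mertk, so the genotype labels could not be checked. Shares below are percent of counts, given as mean ± SD of the 4 mice of a group, and adjusted p-values of genera and ASVs are from edgeR's quasi-likelihood test.

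Bacteroidota and Firmicutes held most counts in every group, with 40.3% ± 4.13 and 50.1% ± 5.21 in WT mice on water. Their ratio (Firmicutes over Bacteroidota) was 1.26 and 1.21 in WT mice on water and DSS and 1.36 and 1.29 in KO mice, with no difference beyond the spread between mice (exact permutation p of 0.514 to 0.743 in the 4 pairwise comparisons). Over all mice, the 10 most abundant genus-level groups were unclassified Muribaculaceae (20.6%), unclassified Lachnospiraceae (14.7%), Lachnospiraceae_NK4A136_group (10.3%), Lactobacillus (5.33%), Alistipes (4.53%), Prevotellaceae_UCG-001 (3.84%), Bacteroides (3.44%), unclassified Oscillospiraceae (3.17%), Helicobacter (2.69%) and Rikenellaceae_RC9_gut_group (2.39%). These means pool unlike groups: single mice ranged from 0.131% to 14% in Prevotellaceae_UCG-001, and from 0% to 8.90% in Helicobacter, which was nearly absent from KO mice on water.

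**Figure D1:**
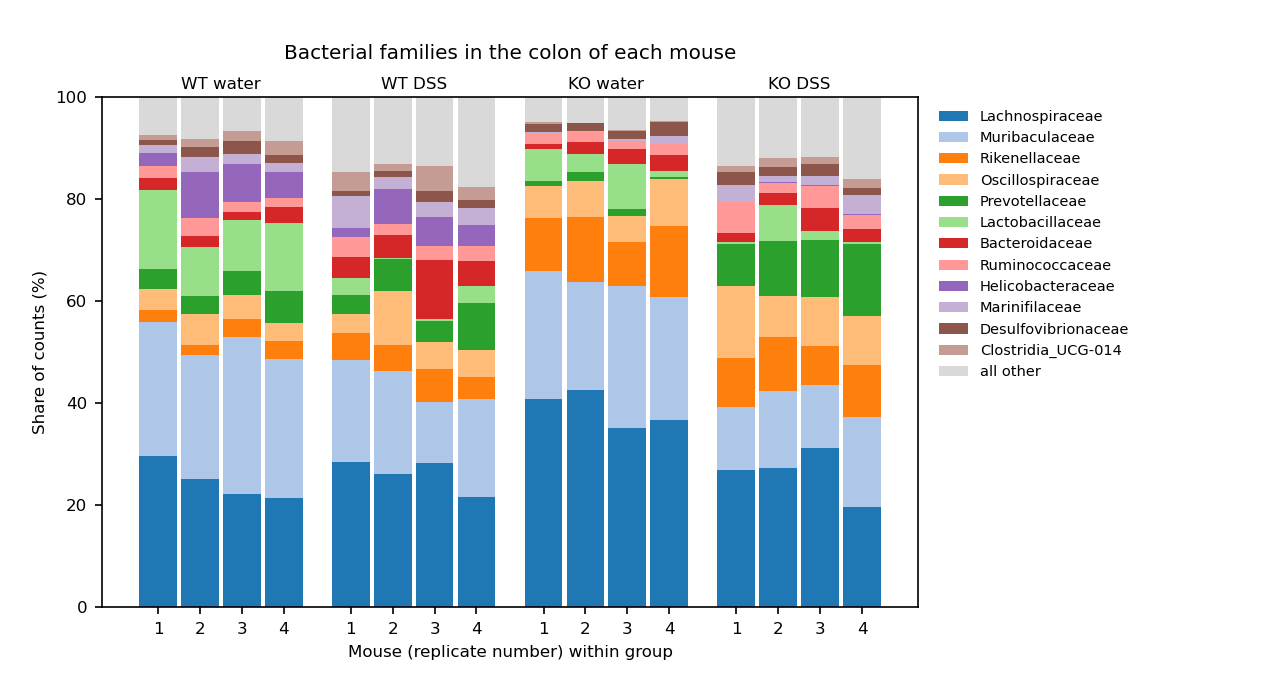
Stacked bars give the share of counts (percent, vertical axis) of the 12 families with the highest mean in each of the 16 mice, grouped by genotype and treatment. Helicobacteraceae held 5.99% in WT mice on water and 0.000777% in KO mice on water, and Prevotellaceae held 11.04% in KO mice on DSS.

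Mice separated by genotype and by treatment. On Bray-Curtis distances (0 for identical, 1 for no shared ASVs), genotype took a share of the squared distance (R2) of 0.4457, treatment 0.1701 and their interaction 0.1166 in a permutation analysis of variance with both factors (p = 1e-04, the smallest possible, 2e-04 and 0.0037). On distances of genera the order turned, with R2 of 0.2671 for genotype, 0.3139 for treatment and 0.0849 for the interaction (permutation p = 1e-04, 1e-04 and 0.0175). The mean distance between a KO and a WT mouse was 0.849 on water, against 0.445 within KO and 0.352 within WT mice. The Shannon index of ASVs was 4.85 ± 0.0494 in WT mice on water, 4.44 ± 0.257 in WT mice on DSS, 4.94 ± 0.0639 in KO mice on water and 4.65 ± 0.0449 in KO mice on DSS. The number of ASVs per mouse was 627.5 ± 34.5, 530.2 ± 104, 492 ± 8.83 and 528.2 ± 11.3 in the same order.

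**Figure D2:**
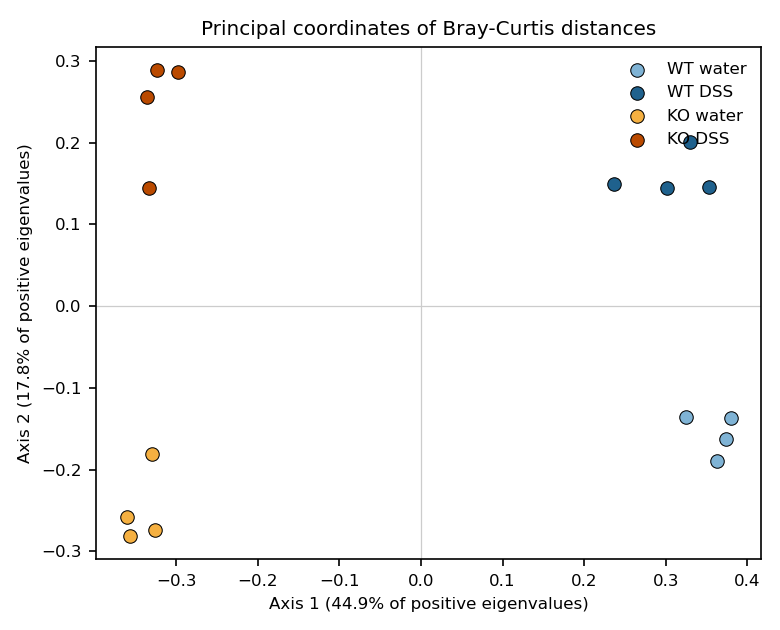
Each point is 1 of the 16 mice on the first 2 principal coordinates of the Bray-Curtis distances, which hold 44.9% and 17.8% of the positive eigenvalues, colored by group. WT mice lie above 0 and KO mice below 0 on the first axis, and DSS mice lie above 0 and water mice below 0 on the second.

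The first comparison asked what DSS did in WT mice. Turicibacter and other Erysipelotrichaceae rose, as did Prevotellaceae_UCG-001, Rikenellaceae_RC9_gut_group and Bacteroides. Lactobacillus, which ferments sugars to lactic acid, Muribaculum and several Lachnospiraceae fell. Turicibacter had no count in any of the 4 water mice and a share of 0.341% ± 0.075 on DSS, at least 110-fold higher (adjusted p = 0.000102). Lactobacillus fell from 12.1% ± 2.80 to 1.87% ± 1.69, 6.47-fold (adjusted p = 0.0361, but 0.0669 with median-ratio size factors, and 0.0525 to 0.108 without any 1 of the water mice or without DSS mouse 2 or 3). Prevotellaceae_UCG-001 rose 9.70-fold, from 0.31% ± 0.239 to 3.01% ± 0.864 (log2 fold change 3.28, SE 0.55, adjusted p = 0.000643), and 15-fold without water mouse 4.

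Of 122 genus-level groups tested, 39 passed an FDR of 0.05 in WT mice, 14 higher and 25 lower on DSS, with a median log2 fold change of -0.28 over all groups (0.16 on centred log-ratios). Of 8 Erysipelotrichales genera, 4 rose and 1 fell (5 adjusted over the list alone). Faecalibaculum went from 0.00181% ± 0.00363 to 3.59% ± 2.99 and Dubosiella rose 30.1-fold, from 0.00622% to 0.187% ± 0.134. Of 45 genera of anaerobic Clostridia families, 1 rose and 8 fell (9 adjusted over the list alone). Among them, Lachnospiraceae_UCG-001 fell from 0.455% ± 0.81 to no count, at least 146-fold but 16.2-fold without water mouse 1, Ruminococcus fell 22.9-fold to 0.0542% ± 0.0301, and Lachnoclostridium fell 6.73-fold to 0.0796% ± 0.032 (adjusted p = 0.0513 without DSS mouse 3). Of 8 genera on the butyrate-producing list 1 rose (1 adjusted over the list alone). That list was matched on whole genus names. It leaves out [Eubacterium]_ventriosum_group and [Eubacterium]_xylanophilum_group, which fell. Both groups of Muribaculaceae fell (2 adjusted over the list alone). Muribaculum fell 11.8-fold to 0.0653% ± 0.0643 (20.8-fold without DSS mouse 4). Unclassified Muribaculaceae fell 1.48-fold, from 26.4% ± 2.66 to 17.8% ± 3.89, a change that did not pass with TMM scaling (adjusted p = 0.125) or without any 1 of water mice 1, 3 and 4 and DSS mice 3 and 4 (0.0564 to 0.164), and was log2 0.01 on centred log-ratios. Of 3 Gram-positive cocci, 2 fell (2 adjusted over the list alone), with Staphylococcus from 0.514% ± 0.575 to 0.00259% ± 0.00299. Of 3 mucin-degrading genera, 2 rose (2 adjusted over the list alone). Bacteroides rose 2.70-fold to 6.22% ± 3.45 (not passing without water mouse 3 or DSS mouse 3, adjusted p = 0.0663 and 0.119), and Akkermansia went from no count to 0.0345% ± 0.0201, a call lost when traces of the other DSS group were set to 0 (adjusted p = 1).

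One of 3 Rikenellaceae, Rikenellaceae_RC9_gut_group, rose 5.91-fold to 3.08% ± 0.74, and 1 of 3 sulfate reducers, unclassified Desulfovibrionaceae, rose 4.62-fold to 0.326% ± 0.138 (each 1 adjusted over the list alone). Unclassified Rhodospirillales rose 15.5-fold to 0.993% ± 0.557 (adjusted p = 0.0521 without water mouse 3). One of 3 Prevotellaceae rose, 1 of 2 genera of lactobacilli and bifidobacteria fell, and 1 of 3 mucus-associated genera fell (1 each adjusted over the list alone). The single tested genera of Enterobacterales, Sutterellaceae and the coprostanoligenes group did not pass. At the level of ASVs, 178 of 1056 passed, 83 higher and 95 lower, with ASV16 (Faecalibaculum), ASV151 (Bacteroides) and ASV63 (Turicibacter) at least 1150-fold, 201-fold and 110-fold higher. ASV77 (Ruminococcus), ASV193 (unclassified Lachnospiraceae) and ASV201 (Lactobacillus) were at least 329-fold, 146-fold and 144-fold lower. Without 1 mouse each (DSS mice 4 and 3 for ASV16 and ASV151, water mice 2, 4 and 3 for the last 3), the bounds were 686-fold, 95.2-fold, 212-fold, 97.3-fold and 90.7-fold. The Shannon index fell by 0.414 (two-sided exact permutation p = 0.0286, the smallest that 4 against 4 mice can give, but 0.0571 without any 1 of the 4 water mice), while that of genera rose by 0.192 (exact permutation p = 0.0286). Genera here include the pooled groups without a genus name. Counts with a genus name held 51.52% to 60.24% on water and 54.21% to 74.22% on DSS. The difference of -97.2 observed ASVs lay within the spread between mice (exact permutation p = 0.143), but was -141.8 without DSS mouse 4 (exact permutation p = 0.0286) and -57.8 without DSS mouse 3 (exact permutation p = 0.286). Communities on water and on DSS differed (R2 0.4971, exact permutation p = 0.0286), and DSS mice lay farther from their centroid (0.288 against 0.216, exact permutation p = 0.0286). Shares separated without overlap in 6 of 15 lists, 6 of 17 families and 2 of 10 phyla (exact permutation p = 0.0286 each), where chance gives 2.86% of taxa. None passed adjustment, which with 4 against 4 mice takes at least 9 lists, 10 families or 6 phyla at that p. With traces set to 0, 34 ASVs were higher and 95 lower, and DESeq2 gave 119 higher and 74 lower. Without WT DSS mouse 1, 114 ASVs passed.

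**Figure D3:**
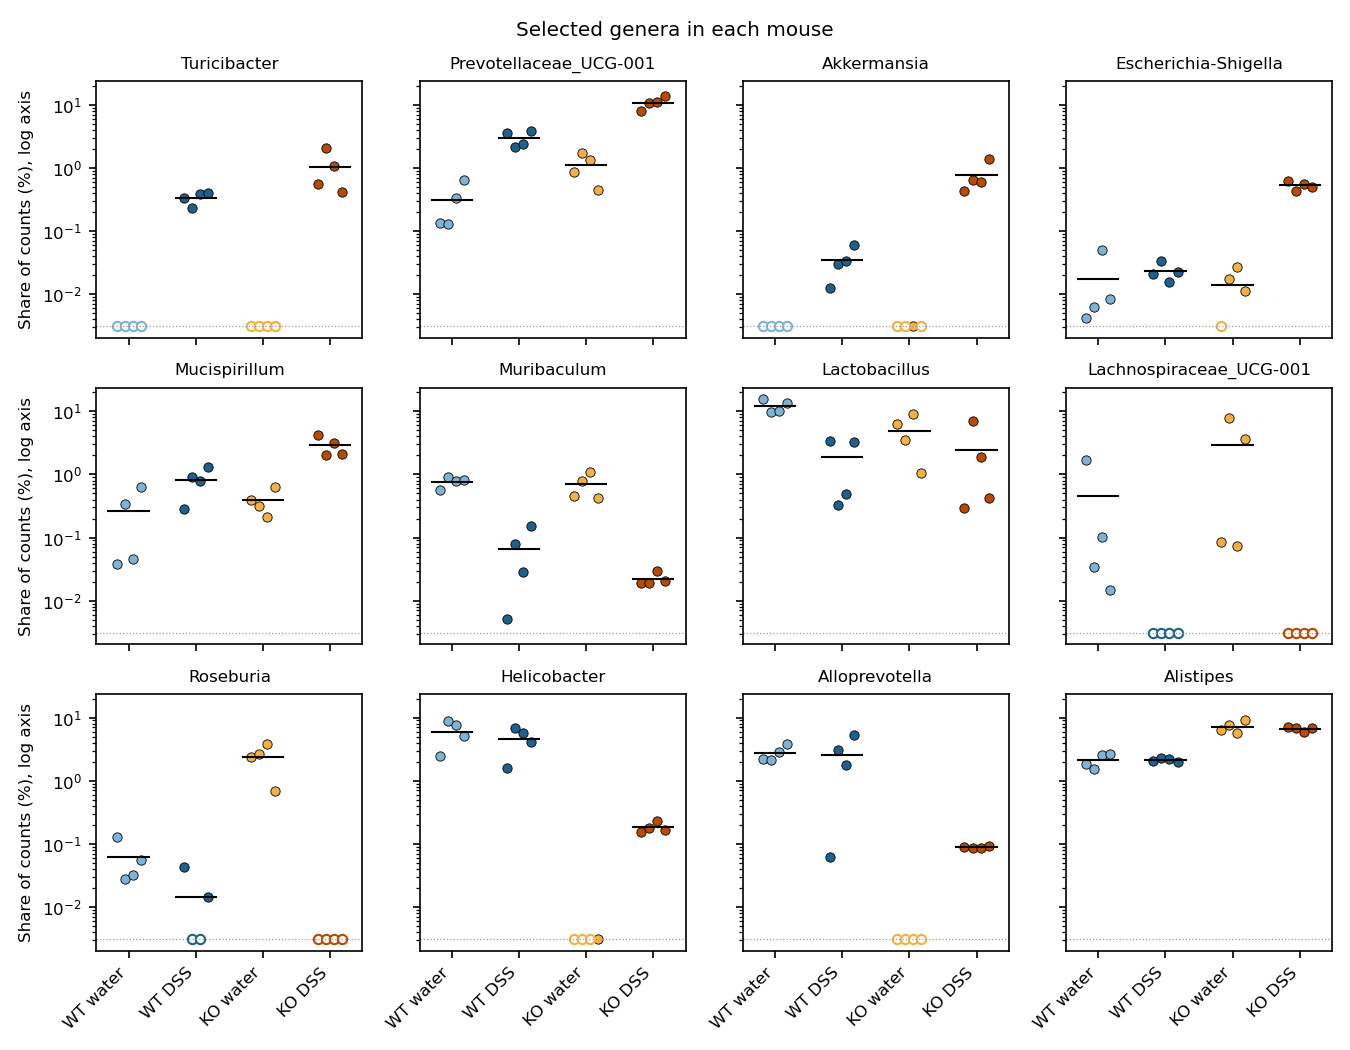
Points are the shares of counts (percent, log axis) of 12 genera in each mouse, lines are group means where above the dotted floor of 3 counts (0.00311%), and open points on that floor are libraries with fewer than 3 counts. Turicibacter is on the floor in all 8 water mice and between 0.235% and 2.11% in the 8 DSS mice.

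The second comparison asked the same in KO mice. Turicibacter, Akkermansia, Escherichia-Shigella, Mucispirillum and Prevotellaceae_UCG-001 rose, while several Lachnospiraceae, Bifidobacterium and Muribaculum fell. Turicibacter went from no count to 1.04% ± 0.763, at least 336-fold higher (adjusted p = 1.84e-05) and 222-fold without DSS mouse 2. Akkermansia, a degrader of mucin, went from 0.000777% ± 0.00155 to 0.767% ± 0.427 (adjusted p = 7.75e-05). Escherichia-Shigella, facultative anaerobes, rose 38.0-fold, from 0.014% ± 0.0113 to 0.532% ± 0.0838 (log2 fold change 5.24, SE 1.08, adjusted p = 0.00124). Roseburia, a butyrate producer, fell from 2.40% ± 1.31 to no count, at least 772-fold (adjusted p = 0.00016).

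In KO mice, 40 genus-level groups passed, 21 higher and 19 lower on DSS. Of 45 genera of anaerobic Clostridia families, 1 rose and 9 fell (9 adjusted over the list alone). Lachnospiraceae_UCG-001 fell from 2.90% ± 3.67 to no count, at least 933-fold but 409-fold without water mouse 2, and [Eubacterium]_ventriosum_group, A2, Marvinbryantia and [Eubacterium]_xylanophilum_group also fell to no count, at least 113-fold, 104-fold, 69.3-fold and 61.3-fold (A2 at least 32.8-fold without water mouse 1). Blautia fell 4.70-fold to 0.156% ± 0.153, a call lost with TMM scaling and with traces set to 0 (adjusted p = 0.0793 and 0.0597). It was 9.16-fold without DSS mouse 1, and did not pass without any 1 of mice 2 to 4 of either group (adjusted p = 0.0611 to 0.12). [Eubacterium]_siraeum_group rose to 2.30% ± 1.87, 68.2-fold over a water mean that mouse 1 sets (0.134%), and without that mouse the water mean is under 3 counts and no fold can be given. Of 8 genera on the butyrate-producing list, which leaves out the [Eubacterium] groups, Roseburia alone passed (1 adjusted over the list alone). Of 3 Prevotellaceae, 2 rose (3 adjusted over the list alone). Prevotellaceae_UCG-001 rose 9.93-fold, from 1.10% ± 0.567 to 10.9% ± 2.42, and Alloprevotella went from no count to 0.0879% ± 0.00259. Of 3 mucus-associated genera, 2 rose and 1 fell (3 adjusted over the list alone). Mucispirillum, which lives in the mucus layer, rose 7.40-fold to 2.88% ± 1.04, and Helicobacter went from 0.000777% ± 0.00155 to 0.182% ± 0.0346. The calls of Helicobacter and Alloprevotella ended when traces of the other DSS group were set to 0 (adjusted p = 0.128, with the sign reversed, and 1).

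Of 8 Erysipelotrichales genera, 2 rose and 1 fell (3 adjusted over the list alone). Both groups of Muribaculaceae fell (2 adjusted over the list alone), with Muribaculum 31.9-fold lower and unclassified Muribaculaceae 1.67-fold lower at 14.3% ± 2.48, the latter not passing with TMM scaling or on centred log-ratios (adjusted p = 0.137 and 0.0696). Bifidobacterium fell 70.7-fold to 0.00829% ± 0.0145 (44.6-fold without water mouse 3, and to a mean under 3 counts without DSS mouse 2), 1 of 2 in its list (1 adjusted over the list alone). The single tested genera of Enterobacterales and the coprostanoligenes group rose, and that of Sutterellaceae, Parasutterella, fell 4.73-fold to 0.0622% ± 0.0225 (1 each adjusted over the list alone), the last not passing with TMM scaling (adjusted p = 0.0577) or without water mouse 3 or DSS mouse 1 or 3 (0.0659 to 0.0843). [Eubacterium]_coprostanoligenes_group, named for bacteria that reduce cholesterol to coprostanol, went from 0.000518% ± 0.00104 to 0.238% ± 0.235. Staphylococcus fell at least 8.00-fold, 1 of 3 Gram-positive cocci, and Akkermansia was the 1 of 3 mucin-degrading genera to rise (1 each adjusted over the list alone). No Rikenellaceae or sulfate reducer passed. Anaeroplasma rose 76.1-fold (at least 165-fold without water mouse 4, 50.7-fold without DSS mouse 4), RF39 34.0-fold (50.9-fold without water mouse 1 or 4) and Clostridia_vadinBB60_group 12.6-fold (35.6-fold without water mouse 4). ASVs with no kingdom assigned held 0.105% ± 0.0379 in KO water mice and had no count in KO DSS mice, at least 33.8-fold lower. Of ASVs, 141 passed, 76 higher and 65 lower. ASV63 (Turicibacter), ASV102 (Akkermansia) and ASV120 (Clostridia_UCG-014) were at least 323-fold, 247-fold and 229-fold higher, and ASV29 (unclassified Lachnospiraceae), ASV27 (Lachnospiraceae_UCG-001) and ASV46 (unclassified Muribaculaceae) at least 805-fold, 757-fold and 606-fold lower (ASV27 330-fold without water mouse 2). The Shannon index of ASVs fell by 0.289 and that of genera rose by 0.294 (exact permutation p = 0.0286 each). Counts with a genus name held 48.63% to 54.78% on water and 59.33% to 69.87% on DSS, so fewer counts were pooled on DSS. Whether that raised the index of genera was not tested. Observed ASVs were higher by 36.2 (exact permutation p = 0.0286), by 31.9 without KO water mouse 2 (exact permutation p = 0.0571), and the difference was -22.8 with traces set to 0 (exact permutation p = 0.0571). Communities differed between water and DSS (R2 0.5355, exact permutation p = 0.0286), and the distance to the centroid did not (exact permutation p = 0.514). Shares of 6 of 15 lists, 8 of 17 families and 3 of 10 phyla separated without overlap (exact permutation p = 0.0286 each), too few for any to pass adjustment. With traces set to 0, 64 ASVs passed, 26 higher and 38 lower, and median-ratio size factors gave 93 higher and 50 lower. Without KO water mouse 2 or 3 or KO DSS mouse 3 or 4, 89, 91, 89 and 88 ASVs passed.

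The 2 responses to DSS shared more genera than independent lists would. Of the genera higher in WT and in KO mice, 6 were shared where 2.41 are given by independent lists, and of those lower 12 were shared against 3.89 (one-sided Fisher's exact test, p = 0.0155 and 8.81e-06), with none in opposite directions. These p-values take genera as independent, while the 2 comparisons share 1 fit, and do not measure the spread between mice. The shared risers were Turicibacter, Prevotellaceae_UCG-001, Akkermansia, Dubosiella, Romboutsia and Pseudomonas, the last a genus often found in reagents, at 0.00441% and 0.00466% on DSS and not passing in WT mice with DESeq2 (adjusted p = 0.122). Its calls also ended without any 1 mouse except DSS mouse 3 in WT (adjusted p = 0.0541 to 0.0734) and except DSS mice 1 and 2 in KO mice (0.0614 to 0.0814). Romboutsia, Pseudomonas, [Eubacterium]_brachy_group and Candidatus_Arthromitus were chosen after their values were seen. Among the shared fallers, Lachnospiraceae_UCG-001, Marvinbryantia, A2, [Eubacterium]_xylanophilum_group, [Eubacterium]_ventriosum_group and [Eubacterium]_brachy_group had no count in any of the 8 DSS mice, and Candidatus_Arthromitus, segmented filamentous bacteria, fell to 0% and 0.00674%, the latter not passing without water mouse 1 or DSS mouse 2, 3 or 4 (adjusted p = 0.0503 to 0.127). Of 4 reagent-associated genera, 1 was higher in WT and 2 in KO mice (0 and 2 adjusted over the list alone), and the list held at most 0.0158% ± 0.0167.

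The third comparison asked how KO and WT mice differed without colitis. Helicobacter, a colonizer of the mucus, Alloprevotella and Prevotellaceae_NK3B31_group were abundant in WT mice and at or near no count in KO mice. Alistipes and other Rikenellaceae and Roseburia were higher in KO mice. Helicobacter held 5.99% ± 2.82 in WT and 0.000777% ± 0.00155 in KO mice (adjusted p = 1.56e-07). Alloprevotella, 2.74% ± 0.809 in WT mice, was at least 881-fold lower (adjusted p = 4.5e-06). Alistipes was 3.33-fold higher in KO mice, 7.18% ± 1.5 against 2.16% ± 0.547 (log2 fold change 1.73, SE 0.3, adjusted p = 0.000301).

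On water, 49 genus-level groups passed, 17 higher and 32 lower in KO mice. The split was 8 higher and 31 lower with TMM scaling and 33 higher and 27 lower on centred log-ratios, with median log2 fold changes of -0.15, -0.53 and 0.76 over all groups. All 3 Rikenellaceae were higher (3 adjusted over the list alone), with Rikenellaceae_RC9_gut_group 7.09-fold at 3.69% ± 1.16 and Rikenella 3.61-fold at 0.535% ± 0.205, the last not passing with TMM scaling (adjusted p = 0.131) or without any 1 mouse except KO mouse 2 (0.0566 to 0.099). Of 3 Prevotellaceae, 1 was higher and 2 lower (3 adjusted over the list alone). Prevotellaceae_UCG-001 was 3.56-fold higher (5.49-fold without WT mouse 4) and Prevotellaceae_NK3B31_group, 1.60% ± 0.157 in WT mice, at least 513-fold lower. Of 45 genera of anaerobic Clostridia families, 9 were higher and 7 lower (14 adjusted over the list alone), and of 8 butyrate-producing genera 3 were higher (3 adjusted over the list alone). Roseburia was 39.4-fold, [Eubacterium]_ventriosum_group 27.1-fold, and Anaerotruncus 9.15-fold higher, while Tuzzerella was 11.3-fold lower. Without WT mouse 1 Roseburia was 62.6-fold, without WT mouse 4 [Eubacterium]_ventriosum_group 46.2-fold, and without KO mouse 2 Anaerotruncus 5.49-fold higher, the last not passing (adjusted p = 0.0615). Ruminococcus was 3.87-fold lower, a call lost with TMM scaling and on centred log-ratios (adjusted p = 0.0511 and 0.163) and without any 1 of mice 1 to 3 of either genotype (0.0606 to 0.157). Intestinimonas (7.56-fold), ASF356 (7.06-fold), Marvinbryantia (6.99-fold) and Oscillibacter (3.63-fold) were higher, calls lost with TMM scaling (adjusted p = 0.0573, 0.0942, 0.0973 and 0.0979). Of these, ASF356 did not pass without any 1 of mice 2 to 4 of either genotype (adjusted p = 0.0517 to 0.098), Marvinbryantia without WT mouse 1, 3 or 4 or KO mouse 2 or 3 (0.0566 to 0.0857) and Oscillibacter without WT mouse 1 or 4 or KO mouse 4 (0.0579 to 0.0699). ASF356 was 22.4-fold higher without WT mouse 1 and Marvinbryantia 11.3-fold without WT mouse 2.

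Of 3 groups on the list called sulfate reducers, 2 were higher (2 adjusted over the list alone), and neither passed with TMM scaling (adjusted p = 0.0747 each). The list takes in Bilophila, a bile-tolerant genus, by name and not by its metabolism. Bilophila was 4.52-fold higher at 0.857% ± 0.51. Bilophila did not pass without any 1 of mice 1 to 3 of either genotype (adjusted p = 0.0581 to 0.0744). The coprostanoligenes group, 0.479% ± 0.432 in WT mice, was lower, as were 2 of 3 Gram-positive cocci, 1 of 3 mucin-degrading genera (Parabacteroides, 3.31-fold, adjusted p = 0.153 on centred log-ratios and 0.0657 to 0.0894 without WT mouse 3 or 4 or KO mouse 1), 1 of 3 mucus-associated genera and 2 of 8 Erysipelotrichales, each as many adjusted over the list alone. No Muribaculaceae, lactobacilli, bifidobacteria, Enterobacterales, Sutterellaceae or reagent-associated genus passed. Unclassified Tannerellaceae was at least 163-fold higher. Coriobacteriaceae_UCG-002 was at least 61.7-fold lower, Staphylococcus 20.7-fold (9.31-fold and not passing without WT mouse 1, adjusted p = 0.0716), and Clostridia_UCG-014 8.52-fold. Anaeroplasma was 20.8-fold and Gastranaerophilales 9.32-fold lower, calls lost with traces set to 0 (adjusted p = 0.0601 and 0.0875). That setting changes no water count, so the loss comes from the fit shared by all 16 libraries and the adjustment. WT mouse 2 carries the fold of Anaeroplasma, which was 5.74 without it (adjusted p = 0.236), and it did not pass without KO mouse 1, 2 or 3 (0.0786 to 0.0929) and was at least 45.2-fold without KO mouse 4. Gastranaerophilales did not pass without WT mouse 1 or 2 or KO mouse 1 or 3 (adjusted p = 0.0515 to 0.0756), and was 15.1-fold lower without KO mouse 2. ASVs with no kingdom were 12.7-fold higher, not passing with TMM scaling (adjusted p = 0.081) or without WT mouse 1 or 3 or KO mouse 1, 2 or 3 (0.0512 to 0.0739), and 21.8-fold higher without WT mouse 2. Of ASVs, 558 passed, 220 higher and 338 lower. ASV12 (Rikenellaceae_RC9_gut_group), ASV29 (unclassified Lachnospiraceae) and ASV14 (Alistipes) were at least 898-fold, 805-fold and 790-fold higher, and ASV4 (Helicobacter), ASV5 and ASV23 (unclassified Muribaculaceae) at least 1840-fold, 1430-fold and 990-fold lower. In all, 202 ASVs were in all 4 WT and in no KO mouse and held 56.9% of WT counts, and 124 were in all 4 KO and in no WT mouse and held 43.2% of KO counts. KO mice had fewer ASVs (a difference of -135.5, exact permutation p = 0.0286), and their Shannon index differed by 0.0891 (exact permutation p = 0.0857; 0.0582 without KO mouse 3, exact permutation p = 0.143). Communities differed (R2 0.7055, exact permutation p = 0.0286), and the distance to the centroid did not (exact permutation p = 0.171). In shares, 7 of 15 lists, 7 of 17 families and 3 of 10 phyla separated without overlap (exact permutation p = 0.0286 each), too few for any to pass adjustment. The labels give no cage or litter, so genotype and housing could not be separated.

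The fourth comparison asked how KO and WT mice differed under DSS. Akkermansia, Escherichia-Shigella, Prevotellaceae_UCG-001 and Alistipes were higher in KO mice, and Helicobacter, Alloprevotella, Faecalibaculum and Parasutterella lower. Escherichia-Shigella was 23.1-fold higher, 0.532% ± 0.0838 against 0.0231% ± 0.0074 (log2 fold change 4.52, SE 1.04, adjusted p = 0.00475). Akkermansia was 22.2-fold higher (adjusted p = 0.00475) and Prevotellaceae_UCG-001 3.64-fold (adjusted p = 0.0167). Helicobacter was 25.2-fold lower, 0.182% ± 0.0346 against 4.58% ± 2.30 (adjusted p = 0.000616), and Faecalibaculum 47.1-fold lower (adjusted p = 0.0332), a call that ended without WT mouse 4 (28.0-fold, adjusted p = 0.0684) or any 1 KO mouse (0.0587 to 0.0786). In Escherichia-Shigella, Akkermansia, Helicobacter, Alloprevotella and Faecalibaculum the lower group is at 2.12% to 4.49% of the higher. That is the level of the traces that DSS groups share, so these folds may depend on the traces. Once traces are set to 0, the lower group is at 0. The folds against 3 counts are then 171 for Escherichia-Shigella, 247 for Akkermansia, 1470 for Helicobacter and 1150 for Faecalibaculum (adjusted p = 0.000216, 0.000216, 3.86e-06 and 0.00115). The rule picks ASVs by their difference between these 2 groups, so larger folds and smaller p-values follow from it and add no support. That holds for every fold under DSS given with traces set to 0. In Escherichia-Shigella the rule also takes out counts of a genus that all 4 WT water mice held.

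Under DSS, 25 genus-level groups passed, 10 higher and 15 lower in KO mice (19 and 17 with DESeq2). Of 3 Rikenellaceae, 2 were higher (2 adjusted over the list alone), Alistipes 3.13-fold and Rikenella 4.06-fold, the latter not passing with TMM scaling (adjusted p = 0.112) or without WT mouse 1, 2 or 4 or KO mouse 1, 2 or 3 (0.0598 to 0.129). Of 3 Prevotellaceae 1 was higher and 2 lower (3 adjusted over the list alone), with Alloprevotella 29.4-fold lower (18.7-fold without WT mouse 4, at least 830-fold with traces set to 0). The call of Prevotellaceae_NK3B31_group rests on WT mouse 2 (1.04%), without which the log2 fold change is 0.07 (adjusted p = 1). It also ended on centred log-ratios (adjusted p = 0.656) and without any 1 KO mouse (0.0735 to 0.102), and was at least 84.5-fold with traces set to 0. Of 45 genera of anaerobic Clostridia families, 2 were higher and 5 lower (7 adjusted over the list alone), among them UCG-005, 22.8-fold higher at 0.189% ± 0.0317 (34.7-fold with traces set to 0), and Roseburia, at least 4.58-fold lower (1.56-fold without WT mouse 1) but not passing on centred log-ratios (adjusted p = 0.0842). Roseburia was also the 1 of 8 butyrate-producing genera that passed (1 adjusted over the list alone). Of 3 mucin-degrading genera 1 was higher (3 adjusted over the list alone), of 3 mucus-associated genera 1 was higher and 1 lower (3 adjusted over the list alone), and of 8 Erysipelotrichales 2 were lower (4 adjusted over the list alone). The single tested Enterobacterales genus was higher and Parasutterella, of the Sutterellaceae, 10.1-fold lower (1 each adjusted over the list alone). No genus of Muribaculaceae, lactobacilli and bifidobacteria, Gram-positive cocci, sulfate reducers, the coprostanoligenes group or the reagent-associated list passed. Unclassified Tannerellaceae was 35.8-fold higher and Coriobacteriaceae_UCG-002 23.1-fold lower, with the lower group at the level of traces (2.79% and 4.33% of the higher). With these set to 0 the former has a WT mean under 3 counts and no fold can be given, and the latter is 121-fold lower against 3 counts (adjusted p = 0.000243 and 0.000216). These values follow in part from the rule, which picks ASVs by their difference between the same groups.

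Of ASVs, 398 passed under DSS, 201 higher and 197 lower in KO mice. ASV116 (Lactobacillus), ASV178 (Lachnoclostridium) and ASV304 (Clostridia_vadinBB60_group) were at least 93.2-fold, 86.9-fold and 64.2-fold higher, and ASV127 and ASV117 (unclassified Muribaculaceae) and ASV231 (Clostridia_UCG-014) at least 176-fold, 140-fold and 120-fold lower. The bounds were 40.3-fold and 15.2-fold for ASV116 and ASV178 without KO mice 2 and 3, and 61.2-fold and 22.6-fold for ASV127 and ASV231 without WT mice 1 and 3. ASV304, in 3 mice, was 33.8-fold without KO mouse 4 and could then not be tested, nor without KO mouse 1 or 3. Of the ASVs called between genotypes on water and under DSS, 115 were higher and 142 lower in KO mice in both, against 41.9 and 63.1 for independent lists (one-sided Fisher's exact test, p = 1.42e-38 and 2.79e-38), and 6 were called in opposite directions. The test takes ASVs as independent, which those of a mouse are not, so its p-values do not measure the spread between mice. Neither the Shannon index (difference 0.214, exact permutation p = 0.143, but 0.337 and 0.0286 without WT DSS mouse 4) nor observed ASVs (difference -2, exact permutation p = 0.943, and -41.4 to 42.6 without WT DSS mice 3 and 4) differed beyond the spread between mice. Communities differed (R2 0.6482, exact permutation p = 0.0286), and KO mice lay nearer to their centroid (0.239 against 0.288, exact permutation p = 0.0286). Lists, families and phyla separated without overlap in 4 of 15, 4 of 17 and 3 of 10 shares (exact permutation p = 0.0286 each), too few for any to pass adjustment. Many ASVs typical of one DSS group had a low, even level in the other. With such traces set to 0, 450 ASVs passed, a rise that follows from a rule that picks ASVs differing between these groups.

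**Figure D4:**
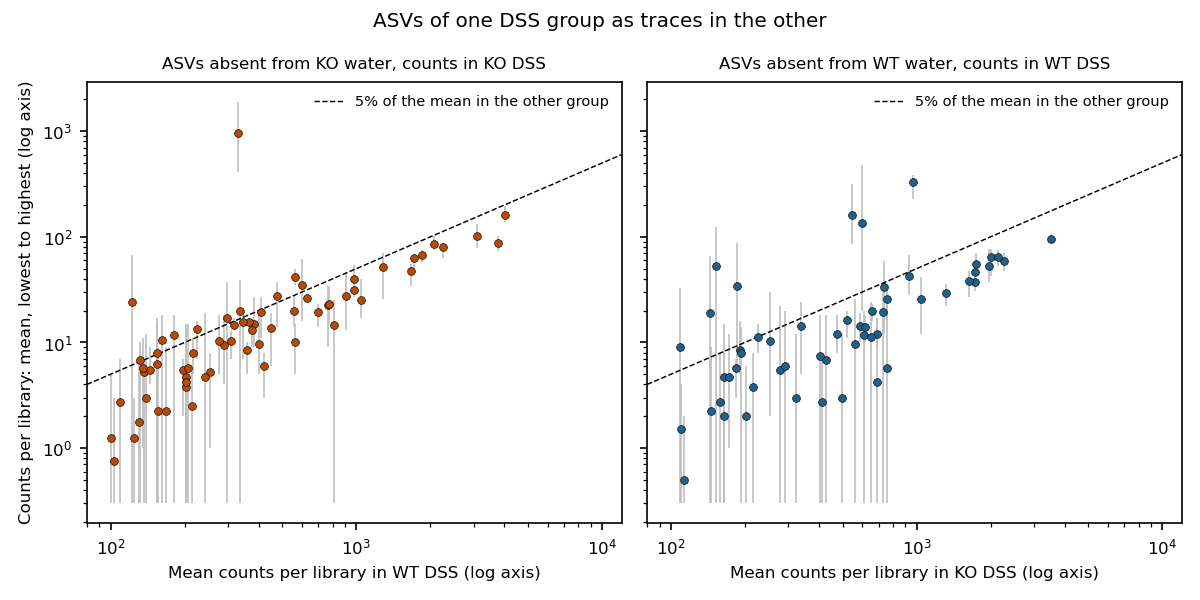
Points are ASVs abundant in one DSS group and absent from the water mice of the other genotype, with mean counts per library in the first group (horizontal) and in the other DSS group (vertical, lines from lowest to highest mouse), both on log axes. Of the 66 and 55 seen, 54 and 48 lie under the dashed line at 5%. Over all seen, the median is 3.39% and 2.59% of the first group's mean.

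The last comparison asked whether DSS acted differently in KO and WT mice. The response of Escherichia-Shigella was larger in KO mice by 4.83 on the log2 scale (SE 1.36, adjusted p = 0.0291, but 0.0513 on centred log-ratios). With traces set to 0 the WT DSS group is at 0. The rule picks ASVs low against KO DSS mice, and all 4 WT water mice held this genus. The larger difference that follows comes from the rule and is no lower bound (fitted 12.33, adjusted p = 0.00275, and 7.73 with that mean set to 3 counts). WT water mouse 3 holds 0.0508%, and without it the difference of 4.83 became 3.37 and did not pass (adjusted p = 0.135). Nor did it pass without WT DSS mouse 1 or 3 or KO DSS mouse 1 (0.0524 to 0.0591). The response of Rikenellaceae_RC9_gut_group was lower in KO mice, by a log2 difference of -3.27 (adjusted p = 0.00363). Rikenellaceae_RC9_gut_group was 0.521% ± 0.266 and 3.08% ± 0.74 in WT mice and 3.69% ± 1.16 and 2.27% ± 1.08 in KO mice on water and DSS. The responses of Roseburia and Faecalibaculum were also lower, with fitted differences of -12.09 and -8.39 (adjusted p = 0.00244 and 0.037) that rest on a group at 0 or under 3 counts per library. With such a mean set to 3 counts the differences are -7.50 and -7.70. That of Roseburia was then -8.16 without WT water mouse 1 and -5.94 without WT DSS mouse 1. Roseburia also fell in WT mice, by a log2 fold change of -2.10 against -9.59 in KO mice on these means. WT DSS mice 2 and 3 had no count. Its share on water was 39.4-fold lower in WT than in KO mice, so it could fall less there before the floor. Part of its difference can come from that. The difference of Faecalibaculum fitted as -1.65 without KO water mouse 1 (adjusted p = 0.9998), and did not pass without any 1 of 9 other mice (0.0524 to 0.095). Its KO DSS group is at 0 with traces set to 0, since the rule picks ASVs low against WT DSS mice. The larger difference then follows from the rule (fitted -17.6, adjusted p = 0.00364, and -12.31 with means set to 3 counts). As shares of counts, Prevotellaceae gained 8.73 percentage points more in KO than in WT mice, and Lachnospiraceae, 38.8% ± 3.5 and 26.3% ± 4.81 in KO mice, changed by -13.9 points relative to WT mice (permutation of genotype within treatment, adjusted p = 0.0139 and 0.0162). On a log2 scale of shares these differences were 3.19 and -0.66 (permutation adjusted p = 0.00347 and 0.025). Prevotellaceae_UCG-001 itself rose alike, 9.70-fold in WT and 9.93-fold in KO mice (log2 difference 0.03, adjusted p = 0.9998). It was 3.56-fold higher in KO than in WT mice on water. Alloprevotella and Prevotellaceae_NK3B31_group added to the family in WT water mice and were at or near no count in KO water mice. The differences of the family can thus come from the shares on water, without a larger fold in KO mice.

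In the interaction 11 genus-level groups passed, 6 higher and 5 lower, with a median of 0.37 on the log2 scale over all groups (0.68 with TMM scaling, -0.33 on centred log-ratios). The 5 lowest p-values were those of Helicobacter (log2 8.03, adjusted p = 0.000157), Alloprevotella (9.49, 0.00161), unclassified Tannerellaceae (-6.78, 0.00244), Roseburia and [Eubacterium]_coprostanoligenes_group (8.00, 0.00244). With traces set to 0, Helicobacter, Alloprevotella and unclassified Tannerellaceae no longer passed (adjusted p = 0.37, 1 and 0.299). Nor did Coriobacteriaceae_UCG-002 (6.01, adjusted p = 0.0157, and 1 with traces set to 0). The others were Ruminococcus (3.97, adjusted p = 0.0238) and Lachnospiraceae_UCG-010 (-7.04, adjusted p = 0.0253). The values of Helicobacter, Alloprevotella, unclassified Tannerellaceae, [Eubacterium]_coprostanoligenes_group, Coriobacteriaceae_UCG-002 and Lachnospiraceae_UCG-010 also rest on a group at or near 0, and are 6.25, 4.91, -2.18, 5.73, 1.42 and -2.45 with that mean set to 3 counts. With that mean set so, Alloprevotella was 5.56 without WT DSS mouse 4, [Eubacterium]_coprostanoligenes_group 4.94 without WT water mouse 4 and 4.88 without KO DSS mouse 3, and Lachnospiraceae_UCG-010 -1.53 without WT DSS mouse 3. The fitted values of Helicobacter and [Eubacterium]_coprostanoligenes_group were 10.84 and 10.32 without KO water mice 4 and 1. Ruminococcus did not pass without WT water mouse 2 or WT DSS mouse 3 (adjusted p = 0.0546 and 0.0562), nor Lachnospiraceae_UCG-010 without the latter (0.0562). By list, 1 of 45 genera of anaerobic Clostridia families was higher and 2 lower (3 adjusted over the list alone), 1 of 8 butyrate-producing genera lower (1), 1 of 8 Erysipelotrichales lower (1), 1 of 3 Prevotellaceae higher (2), 1 of 3 Rikenellaceae lower (1) and 1 of 3 mucus-associated genera higher (2). The single tested Enterobacterales and coprostanoligenes genera were higher (1 each), and no other list had a member past the threshold over all groups.

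Of whole-list shares, Enterobacterales (0.511 points more in KO mice), Prevotellaceae and Rikenellaceae (-4.43 points) passed in the interaction (permutation adjusted p = 0.00612, 0.00612 and 0.0347), as did the phyla Deferribacterota (1.93 points, adjusted p = 0.0102) and Verrucomicrobiota (0.731 points, adjusted p = 0.00408) and the family Lactobacillaceae (7.66 points, adjusted p = 0.043). Deferribacterota and Lactobacillaceae passed in points only (log2 differences 0.67 and 1.60, permutation adjusted p = 0.776 and 0.475), and their genera Mucispirillum and Lactobacillus did not pass in edgeR (1.25 and 1.65, adjusted p = 0.5866 and 0.5059). Verrucomicrobiota passed on a log2 scale too (3.94, permutation adjusted p = 0.00204), while its genus Akkermansia did not in edgeR (1.66, adjusted p = 0.9998) and did on centred log-ratios (3.02, adjusted p = 0.0258). On the log2 scale only, Campilobacterota and its family Helicobacteraceae (4.57 each), Clostridia_UCG-014 (2.24), Gram-positive cocci (3.58), mucus-associated genera (3.02) and the coprostanoligenes group (3.35) passed (permutation adjusted p = 0.00204, 0.00347, 0.025, 0.0049, 0.0049 and 0.0276). That scale adds 0.01% to each share, so a share that starts lower can fall less on it. Staphylococcus, of the Gram-positive cocci, went from 0.514% to 0.00259% in WT and from 0.0249% to no count in KO mice. The 3.58 can thus come from the lower KO share on water. Campilobacterota and Helicobacteraceae are the counts of Helicobacter, and neither passed with traces set to 0 (0.32 each, permutation adjusted p = 0.756 and 0.642). Of ASVs, 59 passed, 33 higher and 26 lower. The change in observed ASVs differed by 133.5 (permutation p = 0.0192), and by 94.1 without WT DSS mouse 3 (permutation p = 0.0506). That of the Shannon index did not differ beyond the spread between mice (0.125, permutation p = 0.38), but did without WT DSS mouse 4 (0.248, permutation p = 0.00449). It was 0.0636 and 0.0707 without WT DSS mice 3 and 2 (permutation p = 0.661 and 0.635). The count of genera was 7 without WT DSS mouse 3 and 19 without KO water mouse 4, and 27 on centred log-ratios. With traces set to 0, 8 genera and 23 ASVs passed.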

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

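All tests of explanations here were chosen after the results were seen, 2 of them replaced earlier versions of the same test, and setting traces to 0 is an alternative added after seeing the data, as is setting group means under 3 counts to 3 counts.

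Many ASVs abundant in one DSS group were present at a low, even level in the other. Of 85 ASVs abundant in WT DSS mice and absent from KO water mice, 43 were in all 4 KO DSS mice, and of 70 in the reverse direction 30 were in all 4 WT DSS mice. The median coefficient of variation between receiving mice, over the 66 and 55 of these ASVs seen there, was 0.518 and 0.737. It was 0.985 and 1.17 in resident ASVs matched on mean count (a share of 0.0001 of 10000 matched sets was as low in each, the smallest possible). That argues against spread of bacteria that then vary between mice as residents do, but not against an even spread. Counting error alone gives 0.275 and 0.289, so the levels were less even than counting error would leave them. Trace levels followed the level in the other DSS group (Spearman's rho 0.85 and 0.7 across ASVs, 0.34 and 0.22 with that genotype's water mice), and at most 7.43% of abundant ASVs were such traces in the other pairs of groups against 31.5% and 23.6%, which argues against carry-over in every library. Cross-talk between DSS libraries may thus account for them, while the source of the gain of observed ASVs in KO mice stays open: it was -18.75 with 1 rule for traces in all 4 groups (exact permutation p = 0.0571), but that rule takes out low-level ASVs whatever their source.

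KO and WT mice differed in many ASVs. A batch of the water libraries alone is argued against by 257 ASVs called in the same direction on water and under DSS, with 6 in opposite directions. Separate breeding or housing of the genotypes cannot be told apart from the genotype, since the labels give no cage or litter, and 202 ASVs in all 4 WT and in no KO water mouse could come from either. An effect of the loss of Mertk stays open and untested.

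DSS changed 18 genus-level groups alike in both genotypes. Of the 6 that rose, 5 kept both calls with traces set to 0. The rule takes only ASVs under 5% of the other DSS group, so genera above that level keep their calls whatever the source of their counts. This test therefore cannot decide on cross-talk. A library batch of the DSS groups cannot be told apart from the treatment, since the DSS libraries of both genotypes shared traces. Nor can an effect of cage, since the labels give none and the mice of a group may have shared it. ASVs with no kingdom were in 7 of 8 water and 0 of 8 DSS libraries. An effect of DSS stays open.

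In the pairwise comparisons the real split was the only 1 of 35 with as many genera (39, 40, 49 and 25 in the order of the pairwise comparisons, with at most 1, 1, 1 and 3 in others) and as many ASVs (178, 141, 558 and 398, with at most 0, 1, 0 and 0), so chance was excluded at 0.05 if mice are independent. The labels give no cage, so whether mice of a group are independent is open. In the interaction, 3 of 100 splits gave at least 11 genera (highest other 13) and 6 of 100 at least 59 ASVs (highest other 247), which says nothing about chance, since these splits leave the genotype difference in. The split with 247 kept the KO name in 4 KO water and 2 KO DSS mice, so that its contrast takes in part of that difference, and the 34 splits with equal numbers mix the genotypes and gave 0. With the additive genotype effect removed, on centred log-ratios, the real split was the only 1 of 100 with as many genera (27, highest other 2) and as many ASVs (299, highest other 5), which excludes chance at 0.05 for those counts, again if mice are independent.

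The response to DSS differed between genotypes by an interaction test in 11 genus-level groups, with log2 differences of 8.03 (Helicobacter), 9.49 (Alloprevotella), -6.78 (unclassified Tannerellaceae), -12.09 (Roseburia), 8.00 ([Eubacterium]_coprostanoligenes_group), -3.27 (Rikenellaceae_RC9_gut_group), 6.01 (Coriobacteriaceae_UCG-002), 3.97 (Ruminococcus), -7.04 (Lachnospiraceae_UCG-010), 4.83 (Escherichia-Shigella) and -8.39 (Faecalibaculum). Those of Ruminococcus, Escherichia-Shigella and Rikenellaceae_RC9_gut_group apart, these are fitted values with a group at or near 0. With traces set to 0, Helicobacter (-2.43), Alloprevotella (0.07), unclassified Tannerellaceae (-3.48) and Coriobacteriaceae_UCG-002 (-0.99) no longer passed (adjusted p = 0.37, 1, 0.299 and 1). Ruminococcus, Lachnospiraceae_UCG-010, Escherichia-Shigella and Faecalibaculum did not pass without some 1 mouse, with 3.37 for Escherichia-Shigella without WT water mouse 3 and -1.65 for Faecalibaculum without KO water mouse 1 (adjusted p = 0.135 and 0.9998). It differed in percentage points in Deferribacterota and its family Deferribacteraceae (1.93 each), Verrucomicrobiota (0.731), Lachnospiraceae (-13.95), Lactobacillaceae (7.66), Prevotellaceae (8.735), Rikenellaceae (-4.43) and Enterobacterales (0.511). On a log2 scale of shares Deferribacterota (0.67) and Lactobacillaceae (1.60) did not pass (permutation adjusted p = 0.776 and 0.475), while Campilobacterota and Helicobacteraceae (4.57 each), Clostridia_UCG-014 (2.24), Gram-positive cocci (3.58), mucus-associated genera (3.02) and the coprostanoligenes group (3.35) passed on that scale only, the first 2 not with traces set to 0 (0.32 each). The 3.58 of Gram-positive cocci can come from the lower share of Staphylococcus in KO water mice, given the 0.01% added on that scale. The response also differed in observed ASVs (133.5) and in Bray-Curtis distances (R2 0.1166).

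Single mice lay far from the other 3 of their group in 47 of 320 groups of values tested. For normally distributed values about 1 in 20, or 16, would do so. Shares are skewed and often 0, so 16 is not the number that chance gives here. Some are 1 mouse with few counts against 0 in the other 3, such as Akkermansia in KO water mouse 3 (0.00311%). Several share a mouse or a taxon and are not independent. Values are percent of counts. In WT water mouse 1 these were the reagent-associated genera (0.00518), A2 (0.295), ASF356 (0.191), Bifidobacterium (0.21), Lachnoclostridium (0.206) and Lachnospiraceae_UCG-001 (1.67). In the other WT water mice they were Anaeroplasma in mouse 2 (0.446), Escherichia-Shigella, the single tested member of Enterobacterales, in mouse 3 (0.0508), and Faecalibaculum (0.00726) and [Eubacterium]_xylanophilum_group (0.228) in mouse 4. In WT DSS mice they were Prevotellaceae_NK3B31_group (1.04) and unclassified Oscillospiraceae (5.0) in mouse 2, Muribaculaceae (12.0), unclassified Muribaculaceae (12.0), mucin-degrading genera (13.0) and Bacteroides (11.4) in mouse 3, and Anaerotruncus (0.00415) in mouse 4.

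In KO water mouse 1 they were [Eubacterium]_coprostanoligenes_group (0.00207, also as a list), A2 (0.99), Faecalibaculum (0.0549), Lachnospiraceae_NK4A136_group (20.3), [Eubacterium]_siraeum_group (0.134) and unclassified Desulfovibrionaceae (0.375). They were Anaerotruncus in mouse 2 (0.501) and Akkermansia in mouse 3 (0.00311). In KO water mouse 4 they were sulfate reducers and Desulfobacterota (2.67 each), Campilobacterota and Helicobacter (0.00311 each), Anaeroplasma (0.027), Bilophila (0.0933), Butyricicoccus (0.654), Clostridia_vadinBB60_group (0.671), Desulfovibrio (2.34) and GCA-900066575 (1.38). In KO DSS mice they were Blautia (0.384) and Tuzzerella (0.134) in mouse 1, Bifidobacterium (0.0301) and Colidextribacter (1.05) in mouse 2, Cyanobacteria and Gastranaerophilales (0.293 each), Dubosiella (0) and Lachnoclostridium (0.97) in mouse 3, and Butyricicoccus (1.46) and Desulfovibrio (0.84) in mouse 4.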

How the results depend on the processing

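Setting traces to 0 and group means under 3 counts to 3 counts, and leaving out each mouse for named genera, was chosen after seeing the data; the other alternatives were planned. Over the counts of genera and ASVs, diversity values and Bray-Curtis tests, 369 alternative values kept their direction and their side of the threshold (counts: stayed within 1.5 times), 23 moved, 8 no longer passed, 4 newly passed and 9 changed sign. Where no reason is given, the cause was not tested.

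The interaction gave 27 genera on centred log-ratios with either pseudocount, against 11. Centred log-ratios gave 314 and 312 ASVs for DSS in WT mice, 296 and 297 for DSS in KO mice and 299 and 301 for the interaction, against 178, 141 and 59, and DESeq2 gave 131 for the interaction. Keeping ASVs seen in at least 6 libraries, which tests fewer, left 116 for DSS in WT mice and 357 for KO against WT on water. With traces set to 0, 64 ASVs passed for DSS in KO mice and 23 for the interaction. The replicate numbers do not pair the mice (24 pairs of the same number, r from -0.298 to 0.171), and a replicate block gave 81, 368 and 231 ASVs for DSS in WT mice and KO against WT on water and under DSS.

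The Shannon index of genera differed by 0.192 and 0.294 for DSS in WT and KO mice and by -0.0844 for KO against WT on water. The inverse Simpson index differed by -19.67, 22.8 and -10.85 for DSS in WT mice, KO against WT on water and the interaction (permutation p = 0.0571, 0.0286 and 0.193). Observed ASVs for DSS in KO mice differed by 33.7 as Chao1 and -22.75 with traces set to 0 (exact permutation p = 0.0571 each), and for KO against WT under DSS by 1.5 counting ASVs with at least 2 counts.

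With each mouse left out in turn, the interaction gave 7 to 19 genera, DSS in WT mice 114 to 172 ASVs and DSS in KO mice 88 to 142. The Shannon differences were -0.5377 to -0.3531 for DSS in WT mice (exact permutation p = 0.0571 without any 1 of the 4 water mice), 0.1527 to 0.3373 for KO against WT under DSS and 0.0636 to 0.2482 for the interaction. Differences in observed ASVs were -141.8 to -57.83 for DSS in WT mice, 31.92 to 41 for DSS in KO mice, 94.08 to 178.1 for the interaction and -41.42 to 42.58 for KO against WT under DSS, with 0.25 and 2.75 without WT DSS mouse 2 and KO DSS mouse 1.

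Of 100 calls of named genera, 87 passed with TMM scaling, 95 with median-ratio size factors, 94 with DESeq2 (2 did not and 4 had no adjusted p), 93 on centred log-ratios and 85 with traces set to 0, and 71 passed without each mouse in turn. Prevotellaceae_NK3B31_group for KO against WT under DSS ranged from -5.98 to 0.07 (without WT DSS mouse 2). Signs changed for unclassified Muribaculaceae on DSS in WT mice on centred log-ratios (0.01), and with traces set to 0 for Helicobacter on DSS in KO mice (-2.80) and in the interaction (-2.43) and Coriobacteriaceae_UCG-002 in the interaction (-0.99). Of shares, 190 kept their sign and side of 0.05 before adjustment on a log2 scale 5 newly passed 0.05, 7 no longer did, all 12 in the interaction, and 8 changed sign: in the interaction Peptococcaceae (0.1766; 0.204 with traces also set to 0) and Tannerellaceae (0.03335; 0.005909), for KO against WT on water Actinobacteriota (-0.0697), Proteobacteria (-0.422) and Enterobacterales (0.0222), and under DSS Lactobacillaceae (-0.0316), Gram-positive cocci (0.0358; 1.54e-06 with reagent-associated genera removed) and lactobacilli and bifidobacteria (-0.0710). At 96469 counts per library, shares under 0.00311% could not be told from 0.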

Other observations

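The table held 635 ASVs with counts in 1 library only, 3 ASVs assigned to Archaea and 2 assigned to Eukaryota, none of which enters a comparison by name.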
